A study of Mus musculus with 6 samples.

How the data were processed

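Total RNA of 6 primary mouse microglial cultures was extracted with Trizol and RNeasy and labelled with biotin in the manufacturer's kit for amplification in a pair of cycles, per the labels' protocols. Amplification of this kind shortens transcripts, so signals of probes far from the 3' end can be low. The deposited values are linear probe set intensity values of 6 arrays, and the submitters' processing notes name GCOS, the scanner maker's software, without a version. Its summary algorithm and settings are not given in the sources used here, and detection calls were not used here. The mean signal after leaving out the lowest and highest 2% of probe sets was 100.0 on each of the 6 arrays, so each array had been scaled to 1 target. The values were all above 0 and were not on a log scale. By the rule fixed for such values they were used as deposited, and log2 was taken after adding a pseudocount of 16. Differences are on this scale, which understates those of dim genes. No sequencing depth applies to arrays, and the number of arrays limits the precision.

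Groups were taken from the labels: 3 Dap12-deficient and 3 wild-type cultures, numbered by order of deposit within a group, so that numbers pair nothing. Of 45101 probe sets, 64 controls were left out of the tests. Of the others, 34945 had 1 gene symbol in the platform annotation used here, 932 several and 9160 none, and genes were named only from the first kind. Probe sets were tested where the mean over 6 arrays was at or above the 40th percentile (a signal of 8.51), which left 27022. Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), two-sided, with no covariate, and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. The arrays were compared for repeated deposits, and 0 probe sets had a value shared by 2 arrays.

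Gene lists were tested with camera (preset correlation 0.01) over 12875 genes, each with its brightest tested probe set, and adjusted over the 29 of 34 lists that had at least 5 measured genes. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance in a single direction, were run beside it. With an estimated correlation 0 lists passed, and with fry 0 lists passed, although 3 of the 7 lists called by camera had an unadjusted fry p under 0.05. Fry's mixed test, of change in either direction, passed for 9 lists. Older symbols were matched through a gene table of the assembly GRCm38.p6, which was otherwise used only for the order of protein-coding genes. The array annotation names no build, so no coordinates are given. Several list genes without a probe set of a single symbol here were not analysed here. The share of genes with an unadjusted p under 0.05 within 100 places of Tyrobp was compared with that of other genes by Fisher's exact test.

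Groups, tests, lists and alternatives were fixed before the data were examined, as was the rule for the genes named. It took Tyrobp, up to 12 genes per direction past the threshold whose arrays did not overlap, filled up to 8 per direction with the smallest unadjusted p, the 4 members with the smallest p of each list that passed and the 2 of every other list, all sex-linked and strain-variable genes, and the 4 neighbours of Tyrobp with the smallest p. Further genes named were chosen after their values were seen: Mdm2, B4galt7, Olig1, Olig2, Pdgfra, Hcst, Csf1r, Nfkbid, Mag, the members of lists too short to test, and those in the closing section.

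Alternatives were pseudocounts of 1 and 64, quantile normalization, a common median, cyclic loess, no filter, a filter at the 60th percentile, eBayes without trend and with a robust prior, array weights, 1 probe set per gene, leaving out probe sets that can bind several transcripts, a term for the kind of title number, leaving out each array in turn, the other list tests, the mean of all probe sets of a gene, and windows of 50 and 250 genes. A sex term (mean log2 signal of Eif2s3y, Kdm5d and Uty), a myelin term (mean log2 signal of Mbp, Mobp, Mog, Mag and Ugt8a) and a fit without Dap12-deficient arrays 1 and 3 were added after the data were seen. For the oligodendrocyte list and the disease-associated programme, the score per array was also fitted by least squares on the group and the sex term, with a 95% t interval.

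The steps were tested on simulated data with the real means and spreads, 20 runs over 27022 probe sets with 200 changed in each. Changes of log2 1, 1.5, 2 and 3 were recovered in 42.8%, 82.6%, 86.4% and 89.9% of cases, and 7.99% of calls were false, somewhat above the nominal 5%. With nothing changed, 0.05 lists per run were called on average and the neighbours of Tyrobp in 5% of runs. Genes were simulated as independent, which real genes of a list are not. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.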

Results

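RNA from 6 primary mouse microglial cultures was measured on single-colour oligonucleotide arrays, 1 array per culture. Microglia are the resident macrophages of the brain. The cultures fell into 3 that were Dap12-deficient and 3 that were wild-type. Dap12 is an adaptor protein of myeloid and natural killer cells, encoded by Tyrobp, that passes signals of receptors such as Trem2 to the kinase Syk through its ITAM motif. The design implies a single comparison, which asks how the transcripts of microglia lacking this adaptor differ from those of wild-type microglia. The table held 45101 probe sets with a linear, scaled signal. Median signals were 12.3, 14.0 and 11.9 on wild-type arrays 1, 2 and 3, and 16.4, 14.5 and 14.6 on Dap12-deficient arrays 1, 2 and 3. The small number of arrays limits the precision of the values below. The labels do not say whether each culture came from its own animals, so p-values measure the spread between these cultures.

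Tyrobp, the targeted gene, fell in the Dap12-deficient cultures and separated the groups by a wide margin. Its only probe set gave 6083 ± 1032 (SD, n = 3) in wild-type and 106 ± 16.8 (SD, n = 3) in Dap12-deficient cultures. The single arrays gave 5584, 7271 and 5396 against 125, 96.4 and 96.2. The log2 difference was -5.64 (SE 0.20, limma adjusted p = 8.14e-07), lower in 3 of 3 arrays, and the mean signals differed 57.4-fold. Where the probes of this set lie relative to the deleted part of the gene is not given in the sources used here, and whether the remaining signal is transcript or background was not measured.

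Besides Tyrobp, only Zdhhc12, which encodes a member of the DHHC family of protein palmitoyltransferases, passed the threshold. Its only probe set fell from 131 ± 15.6 (SD, n = 3) to 10.95 ± 2.04 (SD, n = 3), a log2 difference of -2.44 (SE 0.19, limma adjusted p = 0.00105), lower in 3 of 3 arrays. Of 27022 probe sets tested, 2 thus passed in limma, with 0 higher and 2 lower in Dap12-deficient cultures. At an unadjusted p under 0.05 there were 2880 probe sets, against 1351 expected with no difference, of which 1904 were higher and 976 lower. The higher share was 66.1% with signals as deposited, 56.2% after quantile normalization, 55.8% with a common median and 48.8% (634 of 1300) with 1 probe set per gene. Of 12875 genes with 1 probe set each, 2111 (16.4%) had arrays that did not overlap between the groups, where chance gives 10%, and of these 971 lay above and 1140 below wild-type. The count of 2 rested on the array set: it was 171 (155 higher, 16 lower) without Dap12-deficient replicate 2 and 15 (2 higher, 13 lower) without Dap12-deficient replicate 1. With a sex term in the model, added after the data were seen, Zdhhc12 no longer passed (log2 difference -2.54, SE 0.56, adjusted p = 0.425).

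**Figure D1:**
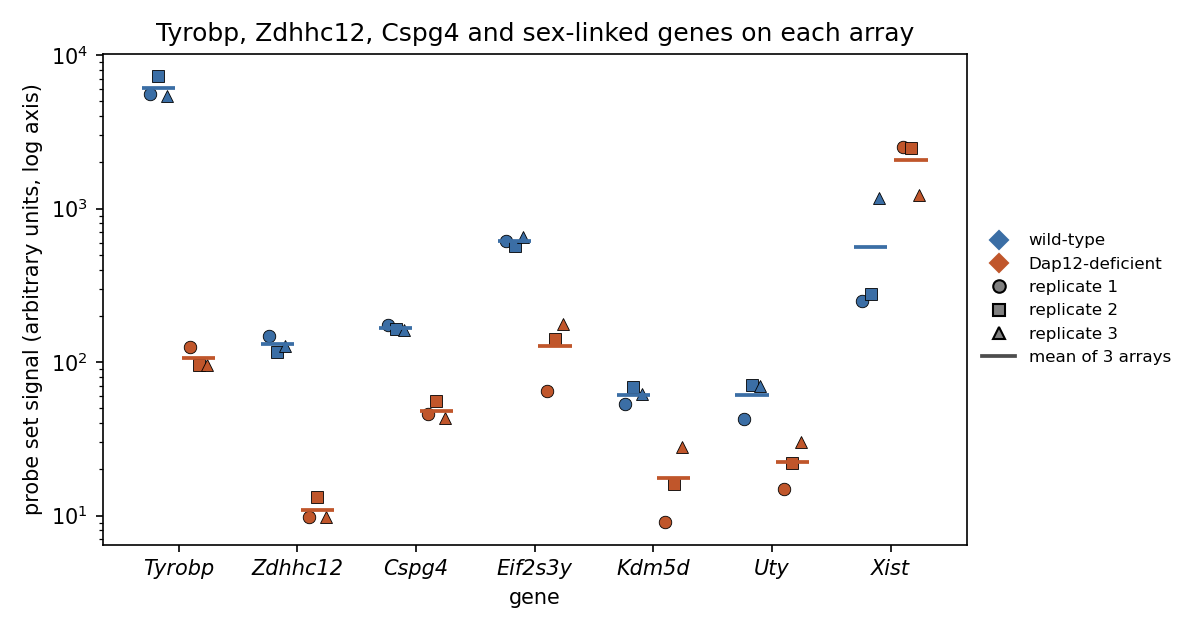
Probe set signal (arbitrary units, log axis) of 7 genes on each of the 6 arrays, with wild-type in blue, Dap12-deficient in orange, a marker shape per replicate and a bar at the mean of 3 arrays. Tyrobp lay between 5396 and 7271 on wild-type arrays and between 96.2 and 125 on Dap12-deficient arrays, and the Y-linked genes lay lower and Xist higher on all 3 Dap12-deficient arrays.

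The genes next in rank, counted by the brightest probe set of each gene, did not pass and are given as values. Among those higher in Dap12-deficient cultures, Cd300lf, an inhibitory receptor of myeloid cells, had a log2 difference of 1.20 (SE 0.20), Cxcl2, a chemokine that attracts neutrophils, 1.77 (SE 0.30), and Cd80, a costimulatory ligand of T cells, 1.12 (SE 0.19). Ncan, a chondroitin sulphate proteoglycan of brain matrix, had 1.91 (SE 0.32), and Ntn1, a secreted guidance cue, 1.33 (SE 0.22). Mcoln3, an endolysosomal cation channel, had 1.16 (SE 0.19). The transcription factors Bhlhe40 and Klf10 had 1.04 (SE 0.18) and 1.25 (SE 0.23). The limma adjusted p of these 8 genes lay between 0.179 and 0.221, and each was higher in 3 of 3 arrays. Lower signals were seen for Cspg4, the NG2 proteoglycan of oligodendrocyte precursors and pericytes (-1.51, SE 0.18, adjusted p = 0.0613), and for the Y-linked translation factor gene Eif2s3y (-2.22, SE 0.29, adjusted p = 0.0998). Egln3, a prolyl hydroxylase acting on hypoxia-inducible factors, had -1.46 (SE 0.23), and Myrf, a transcription factor needed for myelination, -1.30 (SE 0.20). Nudt19, a peroxisomal coenzyme A hydrolase, had -1.35 (SE 0.21), and the serpin gene Serpinb6b -1.59 (SE 0.25). Adjusted p lay between 0.164 and 0.179 for these last 4 genes, and all 6 genes were lower in 3 of 3 arrays. Other tested probe sets of a gene gave smaller differences in both directions: 0.55 and 0.59 for Ncan, 0.44 for Cd80, 0.43 for Ntn1, -0.41 for Cspg4, -0.47 for Nudt19 and -0.59 for Egln3. Probe sets too dim for the test gave 0.41 for Mcoln3 and -0.34 and 0.22 for Cd80. Dimmer probe sets of Mdm2 (1.60, adjusted p = 0.127), Lpl (-1.87, adjusted p = 0.131) and B4galt7 (1.54, adjusted p = 0.160) had smaller p than any of the 8 higher genes.

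Of 29 preset gene lists tested with camera, 7 passed, 2 with members higher and 5 with members lower. The 20 measured genes of inflammatory cytokines and mediators rose as a group in Dap12-deficient cultures, with 14 higher and 6 lower and a median log2 difference of 0.34 (adjusted p = 0.000327). The adjusted p was 0.703 with an estimated correlation. Adjusted over the list alone, 3 genes passed, all higher, and over all probe sets 0 did. Nfkbiz, a regulator of NF-kB target genes, had a log2 difference of 0.99 (SE 0.19), the cytokine Il1a 0.96 (SE 0.20), the prostaglandin synthase Ptgs2 1.21 (SE 0.32) and the cytokine Lif 0.56 (SE 0.20), each higher in 3 of 3 arrays. The mean of the list per array was higher on all 3 Dap12-deficient arrays than on any wild-type array. The exact permutation p of that score was 0.1, the smallest that 3 against 3 arrays allow. The call ended with the sex term (mean 0.48, adjusted p = 0.235) and with a term for myelin genes (mean 0.22, adjusted p = 0.0598), against a mean of 0.32 without them. In the same cultures markers of oligodendrocytes and microglia were lower and those of astrocytes higher on average. The oligodendrocyte, microglia identity and astrocyte scores per array overlapped between the groups.

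Microglial genes fell as groups. Of 21 measured genes of the disease-associated microglia programme, which microglia take up around amyloid and dying cells, 20 were lower and 1 higher, with a median of -0.20 (camera adjusted p = 0.00139). Of 26 genes of microglia identity, 23 were lower and 3 higher, with a median of -0.27 (adjusted p = 0.00646). With an estimated correlation the adjusted p was 0.824 for both lists. The exact permutation p of the score per array was 0.1 for the programme and 0.3 for identity, whose arrays overlapped between the groups. In the first list 4 genes passed when adjusted over the list alone and 0 over all probe sets. These 4 were the cystatin gene Cst7 (-1.28, SE 0.29), the chemokine Ccl6 (-0.91, SE 0.23), the lipoprotein lipase Lpl (-0.91, SE 0.26) and the pyrophosphate transporter Ank (-0.70, SE 0.20). A second probe set of Lpl gave -1.87. In the identity list 0 genes passed by either count. Its members with the smallest p were the receptor Gpr34 (-0.71, SE 0.23), the transcription factor Sall1 (-0.42, SE 0.19), Olfml3 (-0.45, SE 0.20) and the ectonucleotidase Entpd1, which was higher (0.44, SE 0.20). Both calls ended without wild-type replicate 2 (adjusted p = 0.369 for identity and 0.0762 for the disease-associated programme) and without Dap12-deficient replicate 3 (0.165 and 0.339). Mean differences were then -0.11 and -0.17 for identity, against -0.23 with all arrays, and -0.25 and -0.20 for the programme, against -0.33. Both calls also ended with 1 Dap12-deficient array (mean -0.09, adjusted p = 0.499 for identity and mean -0.15, adjusted p = 0.277 for the programme). With the sex term identity no longer passed although its mean was -0.22 (adjusted p = 0.329), and the programme's mean was -0.76. With the myelin term the programme no longer passed (mean -0.26, adjusted p = 0.506). In the same cultures markers of oligodendrocytes were lower and those of astrocytes higher on average, as given further on.

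Cell cycle genes and genes of glycolysis and hypoxia fell as groups too. Of 30 cell cycle genes, 25 were lower and 5 higher, with a median of -0.30 (camera adjusted p = 0.000327, and adjusted p = 0.824 with an estimated correlation). The centromere histone Cenpa had a log2 difference of -0.69 (SE 0.19), Birc5, a component of the chromosomal passenger complex, -0.58 (SE 0.21), the activator of the anaphase-promoting complex Cdc20 -0.74 (SE 0.30) and the spindle protein Nusap1 -0.45 (SE 0.19). The cell cycle score was lower than on any wild-type array on Dap12-deficient arrays 1 and 2 (-0.29 and -0.23), but on array 3 it was 0.12, above wild-type array 1 (0.06). The exact permutation p of that score was 0.2. With the sex term the mean of this list turned to 0.38 from -0.27. Of 21 genes of glycolysis and hypoxia, 16 were lower and 5 higher, with a median of -0.22 (adjusted p = 0.0217, and adjusted p = 0.824 with an estimated correlation). Adjusted over the list alone, 2 genes passed, Egln3 and the mitophagy receptor Bnip3 (-1.02, SE 0.21), and over all probe sets 0 did. Ankrd37, a target of hypoxia-inducible factor, had -0.59 (SE 0.22) and the glycolytic aldolase Aldoa -0.56 (SE 0.22). The call of this list ended without wild-type replicate 2 (mean -0.24, adjusted p = 0.129), without Dap12-deficient replicate 1 (mean -0.22, adjusted p = 0.0585), with 1 Dap12-deficient array (mean -0.23, adjusted p = 0.0551) and with the sex term (mean -0.04, adjusted p = 0.696), against a mean of -0.27 with all arrays. Oligodendrocyte markers were lower and astrocyte markers higher on average in the same cultures.

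**Figure D2:**
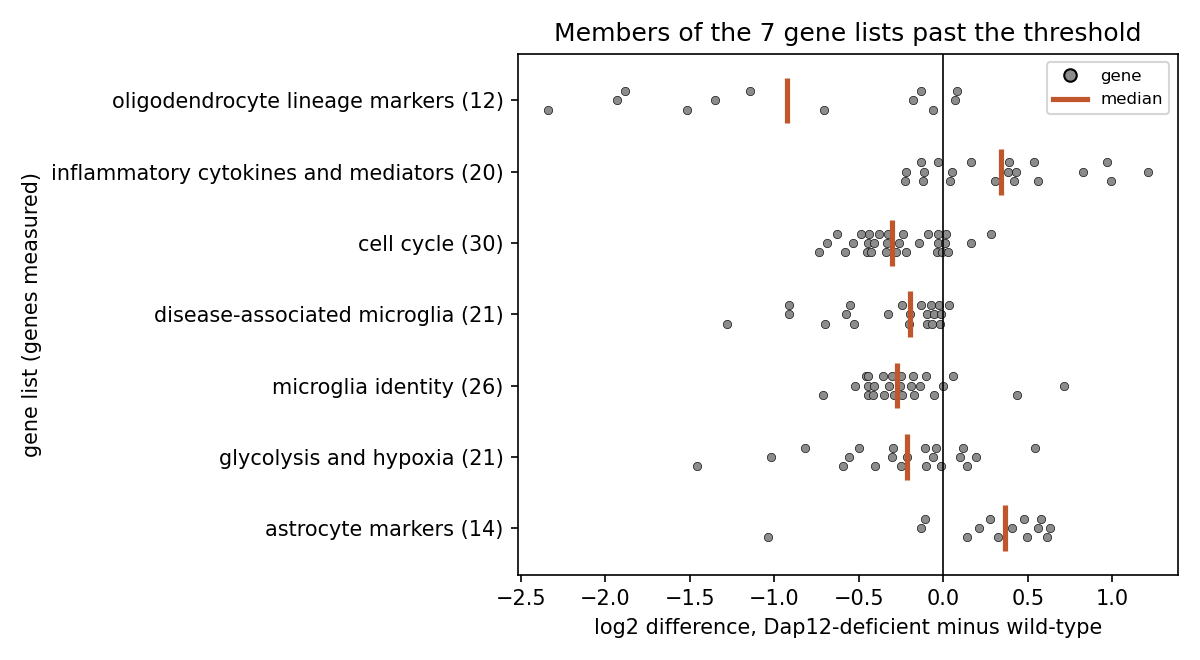
Log2 difference (Dap12-deficient minus wild-type) of each measured member of the 7 lists that passed camera's test, with a grey point per gene, an orange bar at the list's median and the number of genes measured in brackets. Medians lay between -0.93 for oligodendrocyte lineage markers and 0.36 for astrocyte markers, and every list held members on both sides of 0.

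Markers of other brain cells differed between the groups. Oligodendrocyte lineage markers fell as a group, with 10 of 12 measured genes lower and a median of -0.93 (camera adjusted p = 0.000327, and adjusted p = 0.824 with an estimated correlation). Their scores per array overlapped between the groups (exact permutation p = 0.2). Adjusted over the list alone, 3 genes passed, Cspg4 and the myelin genes Mog (-1.88, SE 0.49) and Mobp (-2.34, SE 0.76), and over all probe sets 0 did. Mbp, the myelin basic protein gene, was at 4886 ± 915 (SD, n = 3) in wild-type and 2071 ± 2322 (SD, n = 3) in Dap12-deficient cultures, with 4714, 1142 and 358 on Dap12-deficient arrays 1, 2 and 3. Genes of oligodendrocyte precursors were not alike, with log2 differences of 0.07 for Olig1, 0.08 for Olig2 and -0.06 for Pdgfra, but -1.51 for Cspg4. With the sex term the list still passed and its mean moved to -2.72 from -0.92 (adjusted p = 4.10e-07). That value exceeds the largest difference between arrays in the list's score, 1.71. With the myelin term the list no longer passed (mean -0.17, adjusted p = 0.771). That term is made of members of this list, so such a loss was built in. Astrocyte markers rose as a group, with 11 of 14 genes higher and a median of 0.36 (adjusted p = 0.0309, and adjusted p = 0.824 with an estimated correlation). The astrocyte scores per array overlapped between the groups (exact permutation p = 0.5). They were 0.12, -0.37 and 0.61 on Dap12-deficient arrays 1, 2 and 3, against -0.35 to 0.01 on wild-type arrays. The glutamate transporters Slc1a2 and Slc1a3 had 0.58 (SE 0.22) and 0.63 (SE 0.26), Aldoc 0.48 (SE 0.26), and S100b, which oligodendrocytes also express, -1.04 (SE 0.46). The astrocyte call held under 15 of 25 alternatives and ended without wild-type replicate 2 (mean 0.13, adjusted p = 0.369) and without Dap12-deficient replicate 3 (mean 0.02, adjusted p = 0.561), against a mean of 0.24 with all arrays. The mean was larger without Dap12-deficient replicate 2 (0.49, adjusted p = 0.000491) and with the sex term (0.71), where the call ended (adjusted p = 0.143). With Dap12-deficient array 2 as the lone array of its group, the mean was -0.25.

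**Figure D3:**
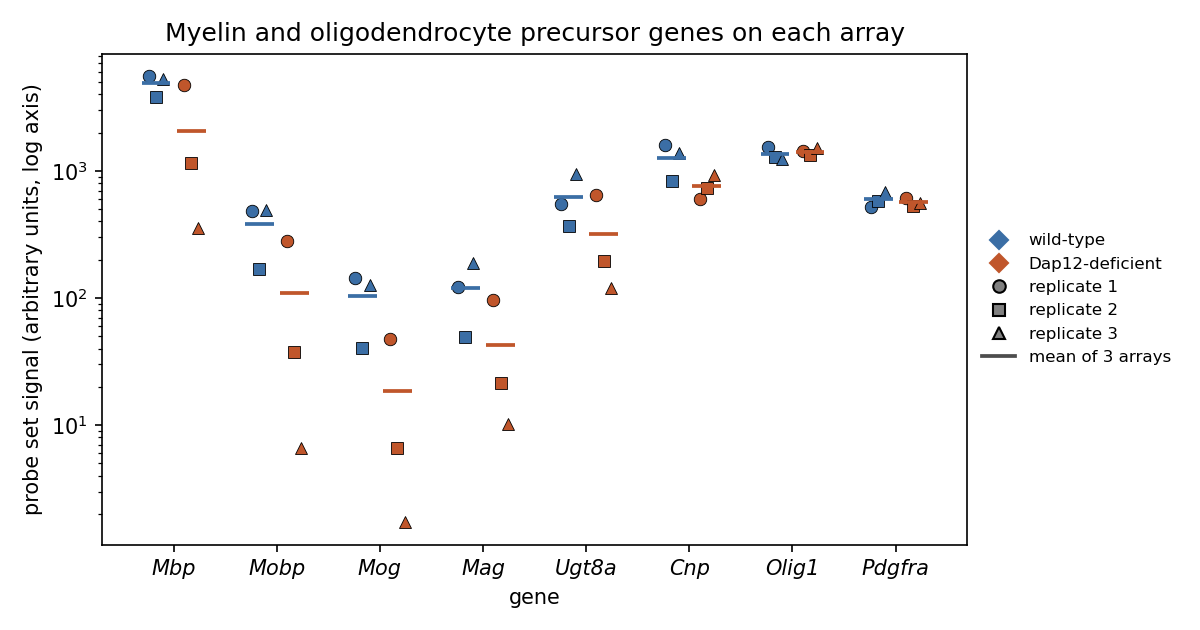
Probe set signal (arbitrary units, log axis) of 6 myelin genes and 2 oligodendrocyte precursor genes on each array, with wild-type in blue, Dap12-deficient in orange, a marker shape per replicate and a bar at the mean of 3 arrays. Mbp reached 4714 on Dap12-deficient array 1 and 358 on array 3, whereas Olig1 and Pdgfra lay close together on all arrays.

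The other lists of neural, vascular and immune cell types did not pass. Neuron markers had a median of -0.25 (camera adjusted p = 0.084), with Tubb3 at -0.64 (SE 0.21) and Gad1 at -0.62 (SE 0.23). Fibroblast and meningeal markers had a median of 0.25 (adjusted p = 0.15), with Postn at -1.03 (SE 0.31) and Islr at 0.69 (SE 0.26). Border macrophage markers had a median of -0.16 (adjusted p = 0.836), with the folate receptor gene Folr2 at -0.78 (SE 0.20) and Cbr2 at 0.68 (SE 0.20). Dendritic cell markers had a median of -0.25 (adjusted p = 0.747), with Flt3 at 0.56 (SE 0.22) and Fscn1 at -0.37 (SE 0.17). Islr and Flt3 were dim, with mean signals of 5.84 and 5.03 in wild-type and 20.8 and 14.2 in Dap12-deficient cultures. Endothelial, lymphocyte and granulocyte markers had fewer than 5 measured genes each and were not tested. Their members with the smallest p were Flt1 (-0.77) and Kdr (0.48), Ighm (-1.33) and Cd79b (-0.04), and Mpo (0.31) and S100a8 (0.27).

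Genes of receptors that pair with Dap12 and of related adaptors, and of signalling proteins downstream, did not pass as groups. The 14 measured genes of the receptor list, which includes the adaptor genes Hcst and Fcer1g, had a median log2 difference of 0.10 (camera adjusted p = 0.322). Trem1, an amplifier of myeloid inflammation, had 0.66 (SE 0.19) and Trem2, a lipid-sensing receptor of microglia, -0.48 (SE 0.22). Hcst, which encodes the related adaptor Dap10, had -0.03 and Csf1r, the receptor of colony-stimulating factor 1, -0.05. The 26 genes of ITAM signalling had a median of -0.12 and a mean of 0.01, so that median and test differed in sign (adjusted p = 0.904). Malt1, a paracaspase of NF-kB signalling, had 0.78 (SE 0.24) and the phosphatase Ptpn6 -0.60 (SE 0.21).

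Among the remaining immune lists, none passed and single members lay on both sides of 0. Chemokines had a median of -0.06 (camera adjusted p = 0.759), with Cxcl2 as above and Cxcl3 at 0.78 (SE 0.20). Interferon-stimulated genes had a median of -0.01 (adjusted p = 0.587), with Mx2 at 0.94 (SE 0.20) and Ifi27l2a at -0.60 (SE 0.23). Cxcl3 and Mx2 were dim, with mean signals of 5.39 and 5.13 in wild-type and 20.6 and 24.6 in Dap12-deficient cultures. Antigen presentation had a median of -0.13 (adjusted p = 0.583), with Cd80 as above and the class II gene H2-Aa at -0.82 (SE 0.19). Phagocytic and scavenger receptors had a median of -0.17 (adjusted p = 0.322), with the scavenger receptor Colec12 at 0.72 (SE 0.17) and the apoptotic cell bridging protein Mfge8 at -0.75 (SE 0.22). Alternative activation had a median of -0.15 (adjusted p = 0.621), with Folr2 as above and the lectin Clec10a at -0.58 (SE 0.20). Complement and coagulation had a median of 0.04 (adjusted p = 0.759), with the matrix protein thrombospondin 1 (Thbs1) at 1.50 (SE 0.41) and C1qa at -0.46 (SE 0.25).

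Lists of cell metabolism, organelles and growth did not pass either. The osteoclast list, a lineage that signals through Dap12, had a median of -0.02 (camera adjusted p = 0.954), with the integrin Itgb3 at -0.87 (SE 0.21) and the carbonic anhydrase Car2, also made by oligodendrocytes, at -1.64 (SE 0.65). Lysosomal genes had a median of -0.04 (adjusted p = 0.59), with the acid lipase Lipa at -0.44 (SE 0.25) and the protease Ctsh at -0.31 (SE 0.19). Lipid efflux and storage had -0.19 (adjusted p = 0.248), with Lpl as above and Mylip at 0.33 (SE 0.17), and cholesterol biosynthesis -0.06 (adjusted p = 0.583), with Pmvk at -0.44 (SE 0.22) and Hsd17b7 at -0.52 (SE 0.31). Actin cytoskeleton and migration had -0.11 (adjusted p = 0.688), with the fibronectin receptor subunit Itga5 at -0.79 (SE 0.20) and Evl at -0.81 (SE 0.30). Growth and neurotrophic factors had 0.08 (adjusted p = 0.621), with Pdgfa at 0.58 (SE 0.20) and Nrp1 at -0.45 (SE 0.19). The synapse and myelin related surface genes had -0.17 (adjusted p = 0.621), with Plxnb2 at -0.68 (SE 0.35) and Slit2 at 0.31 (SE 0.18). Oxidative stress and metal handling had 0.01 (adjusted p = 0.611), with the iron exporter Slc40a1 at 0.63 (SE 0.20) and the NADPH oxidase subunit Ncf1 at -0.73 (SE 0.27). Apoptosis and survival had a median of -0.01 and a mean of 0.16, so that median and test differed in sign (adjusted p = 0.279), with the pro-apoptotic Bcl2l11 at 0.98 (SE 0.33) and Bid at 0.55 (SE 0.19). The immediate early and heat shock list had 0.04 (adjusted p = 0.322), with Hspa1b at 1.20 (SE 0.41) and Jun at 0.43 (SE 0.20).

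Sex-linked transcripts separated the groups. The Y-linked genes Eif2s3y, Kdm5d (-1.23, SE 0.23) and Uty (-1.01, SE 0.23) were lower on 3 of 3 Dap12-deficient arrays, and Xist, the RNA that silences an X chromosome in females, was higher on 3 of 3 (2.14, SE 0.50). Adjusted over the list alone, all 4 measured genes passed, and over all probe sets 0 did. Eif2s3y was at 611 ± 39.3 (SD, n = 3) in wild-type and 127 ± 57.1 (SD, n = 3) in Dap12-deficient cultures. The brightest Xist probe set was at 564 ± 520 (SD, n = 3) and 2075 ± 733 (SD, n = 3). On it, wild-type array 3 (1164) lay close below Dap12-deficient array 3 (1228). On another Xist probe set wild-type array 3 was at 99.8, and Dap12-deficient arrays 1, 2 and 3 were at 2571, 427 and 594. X-linked genes other than Xist had an unadjusted p under 0.05 in 37 of 400 cases (9.25%), and autosomal genes in 1151 of 11925 (9.65%). The genes that vary between laboratory strains had log2 differences of 0.33 (SE 0.20) for Nnt, 0.50 (SE 0.25) for Casp4 and -0.20 (SE 0.19) for Wdfy1, none of which passed.

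Genes beside Tyrobp were examined because a targeted locus can carry flanking DNA of another strain. Among 112 measured genes within 100 places of Tyrobp in gene order, 17 (15.2%) had an unadjusted p under 0.05, against 1174 of 12216 other genes (9.61%). The odds ratio was 1.68 (95% confidence interval 0.94 to 2.85, two-sided Fisher's exact p = 0.0534), which did not pass. Of 826 windows of the same kind elsewhere, 18 (2.18%) had a share at least as high. Neighbouring windows shared most of their genes, so this share is not a p-value. The neighbours with the smallest p were the protease gene Hpn (-1.21, SE 0.27), Aplp1, a relative of the amyloid precursor protein 3 places from Tyrobp (-1.06, SE 0.25), Sbsn (-0.91, SE 0.22) and the splicing factor Hnrnpl (1.08, SE 0.27). Hcst, the gene next to Tyrobp, had -0.03 and Nfkbid, the next but one, 0.01. The 17 also include the myelin gene Mag (-1.35, SE 0.52), 32 places from Tyrobp, so the lower myelin genes enter this count. The test passed under 12 of 24 alternatives, some of which were added after the data were seen. The odds ratio was 2.91 (Fisher's exact p = 3.58e-05) without Dap12-deficient replicate 3 and 1.32 (Fisher's exact p = 0.351) without wild-type replicate 3.

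The Dap12-deficient arrays were more spread out than the wild-type arrays. Correlations between arrays lay between 0.977 and 0.981 within wild-type, between 0.955 and 0.969 within Dap12-deficient cultures and between 0.950 and 0.979 across the groups. Dap12-deficient arrays 1 and 3 lay farthest from the rest on the first principal components, which held 37.5% and 24.7% of the variance. The ratio of 3' to 5' signal of actin, a measure of RNA quality and labelling, was 3.26 ± 0.75 (SD, n = 3) in wild-type and 2.47 ± 0.70 (SD, n = 3) in Dap12-deficient cultures (exact permutation p = 0.2), and that of GAPDH 3.30 ± 0.09 and 3.07 ± 0.53 (exact permutation p = 0.6). The GAPDH ratio was 3.58, 3.09 and 2.52 on Dap12-deficient arrays 1, 2 and 3, against 3.21 to 3.39 on wild-type arrays. The ratio of a spiked bacterial thr control was 3.03 ± 1.88 (SD, n = 3) in wild-type and 1.70 ± 0.81 (SD, n = 3) in Dap12-deficient cultures (exact permutation p = 0.3).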

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

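Apart from the counts over other splits of the arrays, the tests in this part were chosen after the result was seen.

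Among 64 control probe sets, which enter no comparison, 2 were higher on every Dap12-deficient array than on any wild-type array and by more than the spread. A control for the mouse B2 repeat was at 234 ± 4.59 (SD, n = 3) in Dap12-deficient and 185 ± 13.3 (SD, n = 3) in wild-type cultures. A brighter B2 control overlapped between the groups, at 8335 ± 1407 and 8015 ± 1348 (SD, n = 3). A control for the middle part of the mouse pyruvate carboxylase transcript was at 27.6 ± 2.99 (SD, n = 3) and 14.3 ± 1.48 (SD, n = 3). The other pyruvate carboxylase controls did not separate in this way. In all, 4 of 64 controls lay higher on all Dap12-deficient arrays, where chance gives 5% of them. Controls for the bacterial gene bioB, spiked in at hybridization, lay lower: a 3' probe set was at 82.7 ± 7.61 against 125 ± 12.4 (SD, n = 3) in wild-type cultures, and a middle probe set at 156 ± 24.2 against 229 ± 11.5 (SD, n = 3). In all, 5 controls lay lower on all Dap12-deficient arrays.

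The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 2 probe sets past the threshold and the highest other split 0, so 1 split, the real one, reached that count. At an unadjusted p under 0.05 the real split gave 2880 and the highest other 1834, and again 1 split, the real one, reached that count. For gene lists the real split gave 7 and the highest other 10, and 3 splits gave as many. For the neighbours of Tyrobp the real odds ratio was 1.68 and the highest other 3.04, and 3 splits gave one as high.

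Y-linked transcripts were lower and Xist was higher in the Dap12-deficient cultures. Arrays exchanged between the groups are argued against by Tyrobp, whose lowest wild-type signal was 43.0 times the highest Dap12-deficient signal. Fewer cells from male animals in the Dap12-deficient cultures would lower Y-linked and raise Xist signals. The other tested Xist probe sets were higher too (3.00 and 1.22). Both shifts were thus in the direction of that source, but the sex of the animals is not given in the sources used here, so this stays open. A difference in sex between the groups was not separated from genotype. Within a group, the Y-linked mean and Xist ranked the 3 arrays in opposite order in 1 of 6 cases, counting 3 Xist probe sets in both groups. That order cannot decide the question, since a difference between the groups need not appear among the arrays of a group. With the sex term Zdhhc12 had a log2 difference of -2.54 (95% interval -3.79 to -1.29), against -2.44 without it. The call ended because the SE grew from 0.19 to 0.56. Tyrobp had -6.09 with the term (95% interval -7.36 to -4.82). The intervals of both genes thus lay below 0 within these fits. They cannot decide whether sex was the source, because the term largely followed the group. For the score of the oligodendrocyte list the difference with the term was -2.72 (95% interval -5.07 to -0.37). That exceeds the largest difference between arrays, 1.71, so it lies beyond the data and does not decide on sex. For the disease-associated programme the difference with the term was -0.76 (95% interval -2.25 to 0.74), so sex cannot be told apart there. The sex term shared 88.3% of its variance with the group, so all these fits rest on the little that was left. Other genes and lists were not tested in this way.

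Myelin genes were lower in the Dap12-deficient cultures, with large differences between those arrays. Fewer mature oligodendrocytes among the cultured cells may account for this, but cannot be told apart from lower expression per cell. Of 6 myelin genes measured, 5 fell from Dap12-deficient array 1 to 2 to 3, and a shared order would follow from either. Cnp ran in the reverse order (597, 734 and 933). The 3' to 5' ratios of actin (3.20, 2.40 and 1.81) and GAPDH (3.58, 3.09 and 2.52) fell from array 1 to 3 too, so RNA quality was not separated. A lower share of microglia by itself would raise the transcripts of other cells. Instead, 6 of 6 myelin genes had unadjusted 95% intervals in limma below 0. These genes are the pattern itself, so their intervals are no separate test of that source. The mean per array of the 5 genes of the myelin term overlapped between the groups (exact permutation p = 0.2). The myelin minus astrocyte score differed by -1.80, although its highest Dap12-deficient and lowest wild-type values lay only -0.10 apart. An effect of genotype on oligodendrocytes was not tested.

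Inflammatory mediators were higher while microglial genes were lower. A lower share of microglia cannot be told apart for the mediators. Their lowest Dap12-deficient score lay 0.16 above the highest wild-type score, but astrocyte markers were higher on average too. On Dap12-deficient array 2, however, the astrocyte score was -0.37, below every wild-type array, with a mediator score of 0.14. Which cells made the mediators was not measured. For the microglial genes a lower share of microglia cannot be told apart from lower expression per cell, since both would lower the identity score. The groups overlapped in that score, with the highest Dap12-deficient value 0.0454 above the lowest wild-type value. RNA quality or labelling cannot be told apart either, since the actin 3' to 5' ratio lay outside the wild-type range on 2 of 3 Dap12-deficient arrays, and the GAPDH ratio on all 3, above it on array 1 and below it on arrays 2 and 3. A direct effect of losing Dap12 remains open, as the design names it, and was not separated from these.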

How the results depend on the processing

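The sex term, the myelin term and the fit that leaves 1 Dap12-deficient array were chosen after the data were seen. Tyrobp passed under every alternative run, with log2 differences from -6.09 to -5.17, and Zdhhc12 under 21 of 22, from -3.47 with a pseudocount of 1 to -1.37 with 64, the exception being the sex term. The mean Dap12-deficient signal of Zdhhc12 lies below the main pseudocount. The count of 2 probe sets became 4 with array weights and with 1 probe set per gene (Cspg4 and Eif2s3y added), 11 with the sex term and 5 with the myelin term. Leaving out single arrays gave 2 to 171, the highest without Dap12-deficient replicate 2 and 15 without Dap12-deficient replicate 1. The count of 7 lists became 2 with the sex term, 3 with the myelin term, 4 with 1 Dap12-deficient array, 0 with an estimated correlation and 0 with fry. Leaving out single arrays gave 3 to 9 lists, with 3 without wild-type replicate 2 and 4 without Dap12-deficient replicate 3. The odds ratio of the neighbours of Tyrobp was 1.74 with a pseudocount of 1, 1.97 after quantile normalization, 1.76 after cyclic loess, 2.15 with the filter at the 60th percentile, 1.77 with array weights, 1.72 without probe sets that can bind several transcripts, 2.26 with the myelin term and 2.82 with 1 Dap12-deficient array, all past the threshold. Without single arrays it was 1.32 to 2.91, and with windows of 50 and 250 genes 1.45 and 1.23. Turns of direction were counted only for lists that passed in the main fit or under the alternative. By that count, directions turned for astrocyte markers (-0.25) and interferon-stimulated genes (0.24) with 1 Dap12-deficient array, and for cell cycle genes (0.38) with the sex term. In the fit with 1 Dap12-deficient array, that array is assumed to vary as the wild-type arrays do, and its p-values rest on their spread. The sex term made the SEs 2.85 times larger and turned 16 of 92 named genes, the myelin term turned 4 of 92 and the fit with 1 Dap12-deficient array 1 of 91. The cause of the other differences was not tested. Over single lists and alternatives, 677 results stayed on their side of the threshold, 36 dropped out, 7 came in and 3 turned by that count. Of 25 alternatives each, the calls held in 22 for cell cycle and for oligodendrocyte markers, 21 for inflammatory mediators, 19 for microglia identity, the disease-associated programme and glycolysis and hypoxia, and 15 for astrocyte markers. No paired analysis was possible because the replicate numbers follow the order of deposit. Signals near the filter, at 8.51, lie below the pseudocount, which limits what dim genes can show.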

Other observations

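The genes in this part were chosen after their values were seen, and none passed the threshold over all probe sets in limma. Mdm2, the ubiquitin ligase that restrains p53, had a log2 difference of 1.18 on its brightest probe set (863 ± 230 in wild-type and 1978 ± 514 in Dap12-deficient cultures, SD, n = 3) and 1.60 on another. Mmp12, the macrophage metalloelastase, had -1.22 (SE 0.24, adjusted p = 0.272). Ighm, the heavy chain of IgM, had -1.33 with a mean signal of 192 in wild-type and 67.0 in Dap12-deficient cultures. The myelin protein genes Mal and Tspan2, which were on no list, had -1.58 (SE 0.58) and -1.68 (SE 0.62) on their most strongly differing probe sets, and smaller differences on their other probe sets.

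Transcripts that mark microglia were measured in all 6 cultures. Csf1r was at 7481 ± 1771 (SD, n = 3) in wild-type and 7225 ± 1553 (SD, n = 3) in Dap12-deficient cultures, and the protease Ctss at 8188 ± 2147 and 7822 ± 1622. Aif1 was lower on average, at 2442 ± 373 and 1917 ± 451. Of the 26 microglia identity genes, 23 were lower and 3 higher. The levels of Csf1r and Ctss therefore do not show an equal share of microglia. Fcer1g, which encodes another ITAM adaptor, was at 3021 ± 513 and 2289 ± 1234, and Fabp7, a lipid-binding protein of glial precursors and astrocytes, at 1888 ± 360 and 2575 ± 946. The astrocyte filament gene Gfap was at 52.1 ± 23.1 and 116 ± 112.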
